A study of Mus musculus with 6 samples.

How the data were processed

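Single-cell RNA was measured with droplet 3' libraries from live CD45-positive cells sorted from mammary tumours that female mice grew from the injected tumour cell line Py8119. The 6 groups hold 1 library each: intact knockout (KO) mice for Mtdh, intact wild-type (WT) mice, and 4 marrow chimeras that combine KO or WT marrow with a KO or WT host. Per the labels, tumour cells were injected 8 weeks after marrow transfer, tumours grew for 4 weeks and 15000 cells were loaded per library. The groups were taken from the sample labels. In the labels nothing says how many mice stand behind a library. With 1 library per group, spread within a group cannot be measured, and the p-values below rest on differences between libraries.

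The deposited matrices hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger against mm10. Per the file headers the version was 7.0.1 for the intact libraries, with 32285 genes, and 6.1.1 for the transplanted ones, with 31053 genes. The submitters' processing notes also name Seurat. Whether intron reads were counted is not given in the sources used here. The software version coincides with intact against transplanted, and every model of all 6 libraries below carries a term for transplantation. The 30406 gene identifiers shared by all files were used.

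Cells with at least 500 UMIs, at least 200 genes and a mitochondrial share of at most 15% were retained. Doublet scores came from Scrublet in scanpy 1.11.5, run per library. Its automatic threshold called 0 cells in both intact libraries and between 4 and 161 in the others, so, after seeing this, the 6% of cells with the highest scores were removed from each library instead. Of 41267 barcodes, 37992 cells were kept. Counts were normalised and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours gave 45 Leiden clusters at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from marker lists fixed before the data were examined, with a lowest name score of 0.4, and 13 classes were named. A rule added after seeing the data leaves a cluster without a name when its best and second class both reach that score and one is a T or NK class and the other myeloid. It removed cluster 25, which holds 1.91% of the intact KO cells, 0.060% of intact WT, 0.039% of KO marrow in KO host and 0 cells of the 3 remaining libraries.

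UMIs were summed per class and library, because cells of 1 library are not replicates. The summed counts were tested with edgeR 4.0.16 (robust quasi-likelihood, TMM normalisation, filterByExpr) under R 4.3.3, with terms for transplantation, host genotype and immune (marrow) genotype, where an intact mouse carries its own genotype in both. This leaves 2 residual degrees of freedom. With 1 library per group, the error is the disagreement among the 3 matched pairs. The model assumes no host by marrow interaction, and any such interaction enters that error and can hide a change. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05 within each class and term. A matched pair is a KO and a WT library that differ in the tested factor, and each factor has 3 pairs, the intact one included. The intact pair differs in both factors and enters both. Fold changes are log2 with approximate standard errors (SE). Each SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, so it restates that test. Levels are CPM (UMIs scaled to a common library total) with TMM scaling unless stated otherwise. Fixed gene lists, 17 in all and 13 per class, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the correlation estimated, in the transplanted libraries alone, and with fry. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, levels of a single library carry exact Poisson ones, and all of them cover counting error only. Shares were compared by a two-sided exact permutation test of 3 against 3 libraries, which cannot give a p below 0.1.

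After seeing the data, 2 further models were fitted in each class. One has a single term for the 2 libraries in which host and marrow are both KO, beside transplantation, with 3 residual degrees of freedom. The other adds a host by marrow interaction, with 1 residual degree of freedom. The first was chosen because these libraries stood apart from the other 4, so its p-values do not account for that choice.

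The genes named in the text follow a rule written before the data were examined. For each class and factor it takes up to 10 genes per direction that passed the threshold with the largest fold change and 1 sign in all 3 pairs. Where fewer than 10 passed, it fills to 5 with genes of at least 100 UMIs whose smallest pair ratio (10 CPM added) is largest, given as values that did not pass. It also takes up to 4 members per list with a mean of at least 10 CPM, Mtdh, and the 5 most different genes per direction of the intact pair among genes with at least 100 UMIs. Predicted, mitochondrial, ribosomal, haemoglobin and receptor segment genes were left out of all but the list part. The rule was applied to the model for both KO, with its 2 pairs, after that model was chosen. Some genes that the rule takes are not reported here.

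On simulated data with 200 changed genes, the models recovered 30 of 91 genes changed 2-fold and 81 of 95 changed 4-fold for host genotype in CD8 T cells. For macrophages they recovered 41 of 96 and 78 of 97. The simulated means followed each model exactly, without the departures from it that real libraries can hold. The recoveries therefore need not apply to the real tests, where Mtdh, over 4-fold lower in macrophages with KO marrow, did not pass. False calls exceeded the nominal 5%: 11 of 122 calls for host genotype and 23 of 141 for immune genotype in CD8 T cells, 34 of 153 and 15 of 139 in macrophages, and 16 of 155 and 20 of 165 for the model for both KO in CD8 T cells and macrophages.

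Alternatives covered DESeq2 1.42.0, size factors, no count filter, each library left out, the transplanted libraries alone, the other factor left out, cell filters, doublets kept, a gate on marker UMIs and other cluster resolutions. Added after seeing the data were equal cell numbers, CD8 T cells without UMIs of 4 genes of the naive and memory list (called naive genes in the text), the removal of genes 5 times higher in macrophages, monocytes joined to macrophages and another denominator for shares. Figures were drawn with matplotlib 3.10.9. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.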

Results

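The series profiled immune cells of mouse mammary tumours to ask how loss of Mtdh in the host, in the marrow-derived immune cells, or in both, alters them. Each of the 6 groups holds 1 library, with no replicate within a group. The libraries held 122390055 UMIs for intact KO, 142779550 for intact WT, 96375286 for KO marrow in KO host, 85616443 for KO marrow in WT host, 121627871 for WT marrow in KO host and 99532906 for WT marrow in WT host.

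Mtdh, the targeted gene (ENSMUSG00000022255, mm10 chromosome 15, 34082694 to 34145624, plus strand), followed the marrow label in every library. In macrophages it stood at 14.5 CPM in intact KO, 13.8 in KO marrow in KO host and 19.5 in KO marrow in WT host. The libraries with WT marrow held 99.4 CPM in intact WT, 111 in WT marrow in KO host and 115 in WT marrow in WT host. In CD8 T cells the KO marrow libraries held 12.0 to 16.4 CPM and the WT marrow libraries 70.6 to 87.4. The fitted log2 fold change with immune genotype was -2.47 (SE 0.24, adjusted p = 0.000208) in CD8 T cells and -2.71 (SE 0.14, adjusted p = 0.0742) in macrophages, the latter short of the threshold. In the mesenchymal cells, without TMM scaling, Mtdh lay between 369 and 464 CPM in all 6 libraries. It stood at 464 CPM in intact KO, 402 in KO marrow in KO host and 369 in WT marrow in KO host. The WT hosts held 399.7 CPM in intact WT, 426 in KO marrow in WT host and 443 in WT marrow in WT host. The drop seen in KO macrophages is absent. This argues against a host origin of most of these cells, if the KO reaches such host cells. Which part of the gene was deleted is not given in the sources used here, so whether the Mtdh UMIs left with KO marrow are remaining transcript or free RNA is not known. The host label could not be checked, because no class of host cells was identified.

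CD8 T cells took their largest share where marrow was KO. They made up 17.2% (95% interval 16.3 to 18.04) of cells from KO marrow in KO host, 5.53% (4.99 to 6.11) of intact KO and 5.07% (4.51 to 5.68) of KO marrow in WT host. The shares with WT marrow were 2.03% (1.71 to 2.40) in intact WT, 1.92% (1.57 to 2.33) in WT marrow in KO host and 2.80% (2.40 to 3.24) in WT marrow in WT host. Macrophages were the most abundant class, from 47.8% in KO marrow in KO host to 82.6% in intact WT. The CD8 T cell share was higher with KO marrow in 3 of 3 pairs, with a mean log2 ratio of 1.82 (two-sided exact permutation p = 0.1, the smallest this design can give). For host genotype the mean log2 ratio was 0.89 (exact permutation p = 0.5), higher in 2 of 3 pairs. As a share of T and NK cells alone, CD8 T cells had mean log2 ratios of 0.41 with KO marrow and 0.23 with KO host, and T and NK cells together had 1.41 with KO marrow (exact permutation p = 0.1). B cells and cDC2, a dendritic cell class, were also higher with KO marrow in 3 of 3 pairs. Their mean log2 ratios were 2.43 and 0.93 (exact permutation p = 0.2 and 0.1), with only 6 B cells in WT marrow in WT host. The macrophage share was lower with KO marrow in 3 of 3 pairs, with a mean log2 ratio of -0.39 (exact permutation p = 0.1). Shares add to a fixed total, so these changes are not independent of each other.

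**Figure D1:**
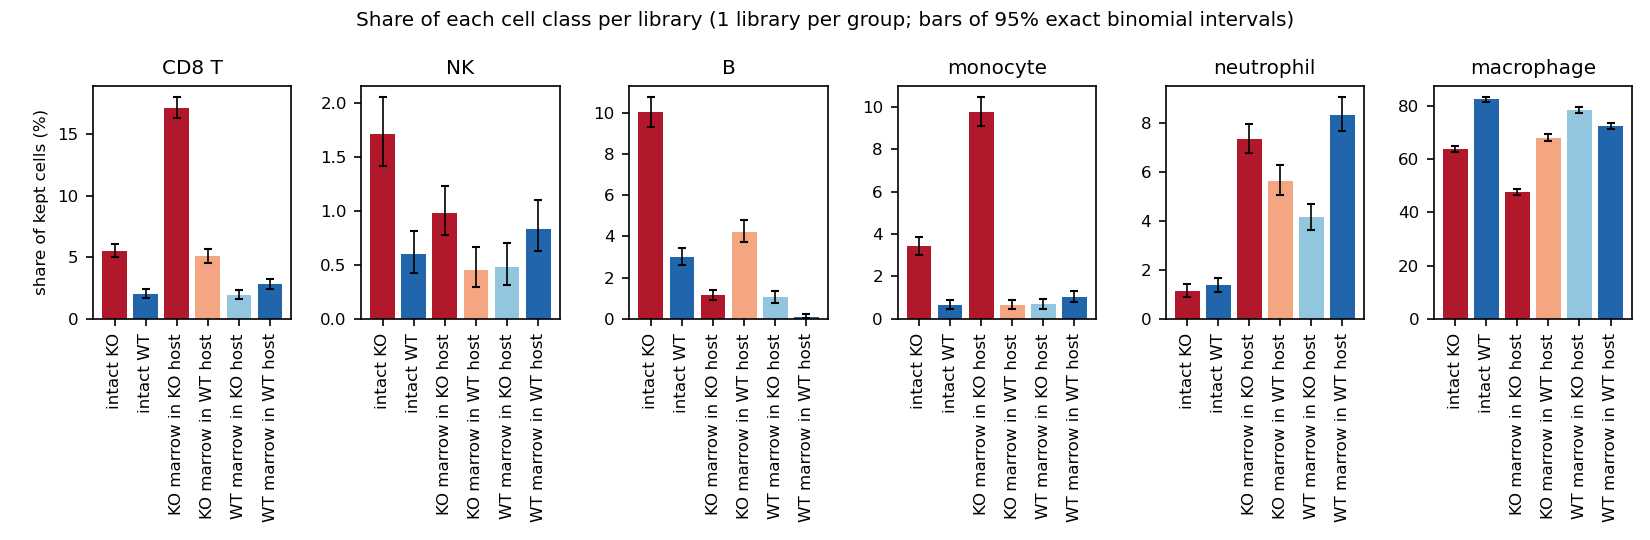
Share of kept cells (%) of 6 classes in each library, with exact 95% binomial intervals as error bars. CD8 T cells reach 17.2% in KO marrow in KO host and 1.92% to 2.80% in the transplanted libraries with WT marrow.

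With a KO host, CD8 T cells held more transcript of several genes of the exhaustion list and of perforin. Rgs16, a regulator of G protein signalling, stood at 233, 279 and 252 CPM in the 3 KO hosts and at 48.3, 45.8 and 73.0 in the 3 WT hosts, a log2 fold change of 2.27 (SE 0.22, adjusted p = 5.38e-05). Nr4a2, a nuclear receptor induced by antigen receptor signals, rose by 1.58 (SE 0.20, adjusted p = 0.000846). Lag3, an inhibitory receptor, rose by 1.78 (SE 0.23, adjusted p = 0.000985), and Tnfrsf9, a costimulatory receptor, by 1.26 (SE 0.23, adjusted p = 0.0186). Prf1, the perforin gene, rose by 2.26 (SE 0.34, adjusted p = 0.0453).

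Of the 16 measured exhaustion genes, 6 rose and 1 fell over all genes tested, and 9 rose and 2 fell adjusted over the list alone. The gene that fell, Eomes, a T-box factor of effector and memory T cells, had a log2 fold change of -1.56 (SE 0.27, adjusted p = 0.00741). The exhaustion list was higher by camera (adjusted p = 1.33e-05, but adjusted p = 0.859 with an estimated correlation). Its median log2 fold change was 0.66 in all cells, 0.36 among cells without UMIs of naive genes (camera adjusted p = 0.0276) and 0.72 among cells with them (camera adjusted p = 0.000665). Of 19 cytotoxic genes 4 rose and 0 fell over all genes, and 6 rose adjusted over the list alone (camera adjusted p = 0.00793, and adjusted p = 0.859 with an estimated correlation). Among cells without UMIs of naive genes the cytotoxic call ended (camera adjusted p = 0.562), with a median of -0.05 and 10 of 19 genes lower, and among cells with them the median was 0.49 (camera adjusted p = 0.000359). Gzmd, a granzyme gene, stood at 337, 1055 and 243 CPM in the KO hosts and at 2.79, 46.4 and 42.2 in the WT hosts, and Gzme, another, at 182, 702 and 215 against 0.929, 11.7 and 22.9. In intact KO their UMIs came from 38 and 27 of 365 cells. Gzma, also a granzyme gene, was lower in all 3 pairs without passing (log2 fold change -2.13, adjusted p = 0.635), and of the list 6 genes were higher and 4 lower in all 3 pairs. The changes of Gzmd and Gzme did not pass over all genes (adjusted p = 0.251 and 0.263) but passed adjusted over the list alone (0.0254 for both). The naive and memory list was lower (camera adjusted p = 0.0182), with 0 of 14 members past the threshold over all genes and 1 higher and 3 lower adjusted over the list alone. The glycolysis list was higher (camera adjusted p = 0.00793) with 0 of 15 members past it either way. Both lists had an adjusted p = 0.859 with an estimated correlation. The T cell receptor response list had no camera call (adjusted p = 0.394), with 0 of 11 higher and 1 lower over all genes and 3 higher and 1 lower adjusted over the list alone. Of 13 dissociation stress genes 1 fell over all genes and 2 adjusted over the list alone, Hspa1a and Hspa1b, both heat shock genes, with no camera call (adjusted p = 0.411). Of 18 interferon genes 1 rose over all genes and 2 adjusted over the list alone, with no camera call (adjusted p = 0.394). The gene that rose over all genes was Cxcl9, at levels near those that free macrophage RNA alone would bring. Without TMM scaling these were 42.0 CPM against 40.9 in intact KO and 42.4 against 54.9 in KO marrow in KO host. In WT marrow in KO host they were 11.1 against 7.68.

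In all, 90 of 9110 genes changed with host genotype in CD8 T cells, 74 higher and 16 lower. Among the largest increases were Serpinb9b, a serine protease inhibitor, Serpine2, another of that family, and the transporters Slc17a6 and Slc16a11. Serpine2 stood at 41.6, 92.9 and 35.2 CPM in the KO hosts and at 1.86, 4.70 and 1.76 in the WT hosts (adjusted p = 3.17e-05). Unc13b, Itgb8, Galnt18, Jam2, Fam178b and Lrrc9 rose as well, from at most 2 UMIs in each WT host library. Ccr2, a chemokine receptor, fell by 1.59 on the log2 scale (SE 0.26, adjusted p = 0.00641) and Myc, a growth regulator, by 1.34 (SE 0.30, adjusted p = 0.0453). Gas7, Tmem176a, S100a9, Kbtbd11 and AB124611 also fell. Cd4 and Cd79b, markers of CD4 T and B cells, were among the lower genes, with Cd4 at 7.53 to 11.7 CPM in KO hosts and 28.8 to 42.8 in WT hosts. For these 2 genes, other cells counted in the class were not told apart from a change within CD8 T cells. H2-Ab1, which is abundant in macrophages and was chosen after its values were seen, rose in CD8 T cells by 1.25 (SE 0.19, adjusted p = 0.00323). The count was 34 when CD8 T cells were gated on marker UMIs, 54 without KO marrow in KO host and 26 among cells without UMIs of naive genes. It was 291 without the count filter, 315 without intact KO, 308 without intact WT, 325 without WT marrow in KO host and 309 without WT marrow in WT host.

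With KO marrow, CD8 T cells differed in 7 genes, 3 higher and 4 lower. Mtdh itself was lower, as were Ccl3, a chemokine (log2 fold change -1.84, SE 0.20, adjusted p = 0.000395), Maf, a transcription factor (-1.66, SE 0.25, adjusted p = 0.0194), and Klra7, an NK cell receptor gene (-1.52, SE 0.26, adjusted p = 0.0475). Gzmg, Serpinb9b and Prss2 were higher, with Gzmg at 14.5, 67.1 and 19.4 CPM in the KO marrow libraries and 0, 1.07 and 0 in the WT marrow ones. Gzmg UMIs came from 2 cells of KO marrow in WT host, 9 of intact KO and 70 of KO marrow in KO host, and Prss2 UMIs from 5 to 13 cells per KO marrow library. H2-Eb1, Cxcl9, Chil3 and Tmem176a each kept its own direction in all pairs without passing. In CD8 T cells C1qa, C1qb and C1qc stood at 2.97% to 4.37% of their macrophage level. Whether such free RNA brought the values of H2-Eb1, Chil3 and Tmem176a was not tested. The interferon and proliferation lists were lower by camera (adjusted p = 0.00548 for both, but adjusted p = 0.976 with an estimated correlation), with 0 of 18 and 0 of 15 members past the threshold over all genes. Adjusted over the list alone, 0 proliferation genes passed and 1 interferon gene, Cxcl9, was higher, at levels near those that free macrophage RNA alone would bring (42.0 CPM against 40.9 in intact KO, without TMM scaling). The count of 7, with 257 genes at an unadjusted p under 0.05 and 7 by DESeq2, was 1 without the host term and 3 without KO marrow in KO host. It was 86 without KO marrow in WT host, 53 without WT marrow in WT host, 37 without intact WT, 35 without intact KO and 23 without WT marrow in KO host.

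**Figure D2:**
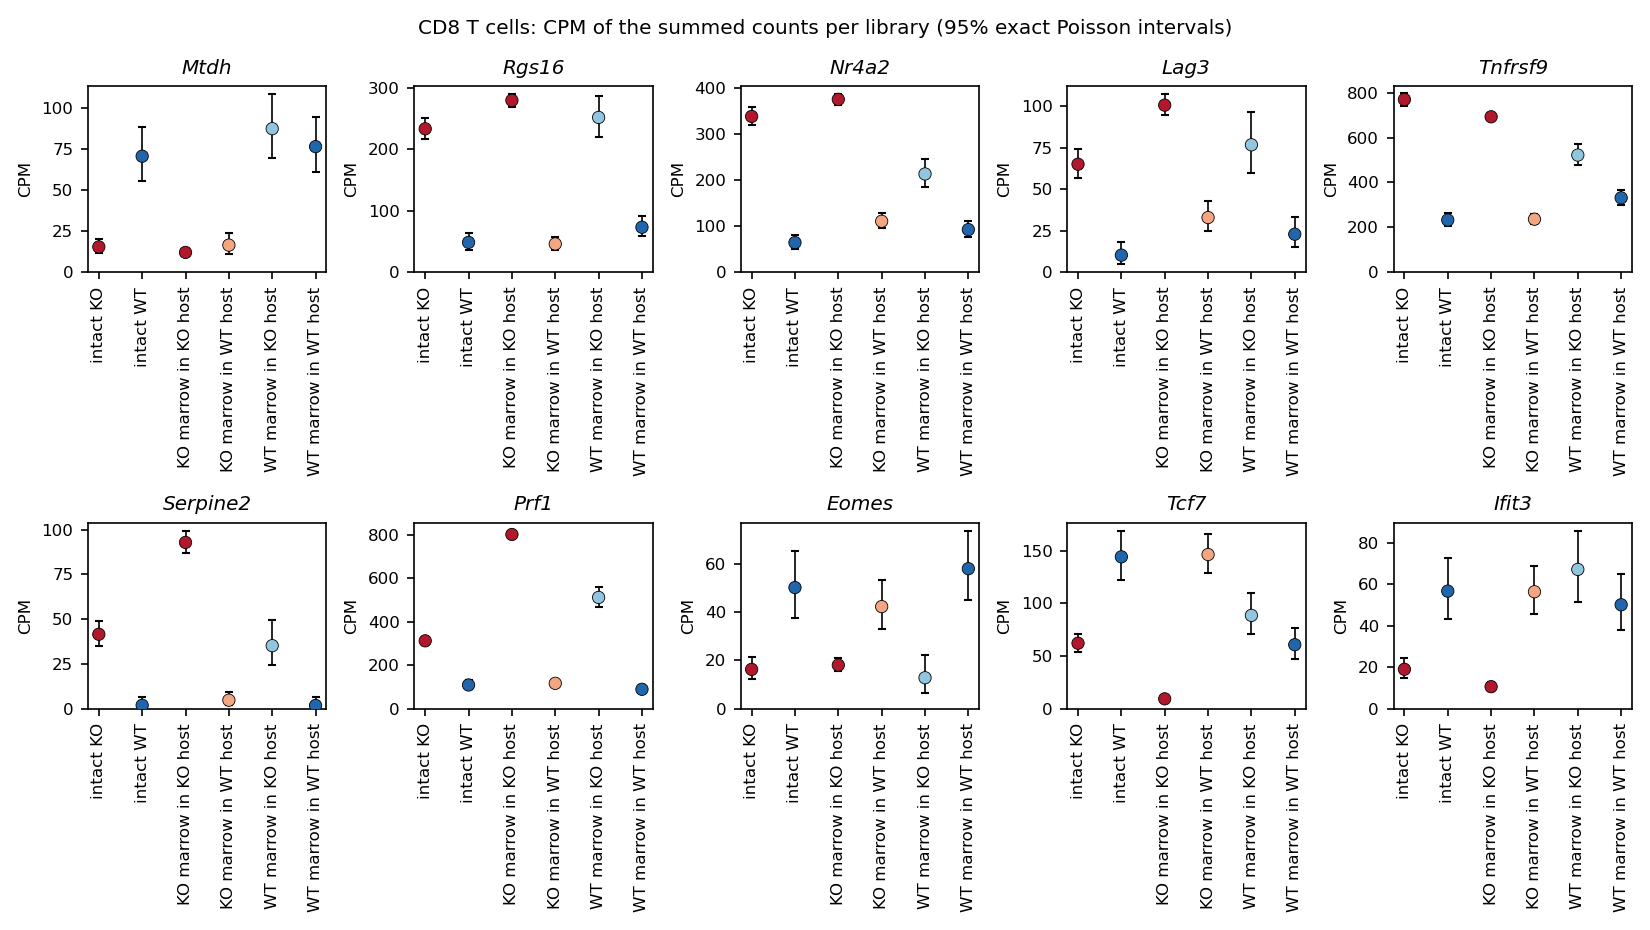
CPM of 10 genes in the summed counts of CD8 T cells, 1 point per library with exact 95% Poisson intervals, in red for host and marrow both KO, dark blue for both WT, orange for KO marrow in WT host and light blue for WT marrow in KO host. Rgs16 lies at 233 to 279 CPM in the 3 KO hosts and at 45.8 to 73.0 in the 3 WT hosts, and Mtdh follows the marrow.

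In macrophages, antigen presentation and interferon genes had higher values in KO hosts and with KO marrow. Cxcl9, an interferon-induced chemokine that attracts T cells, stood at 1306 CPM in intact KO and 107 in intact WT, and at 178 in WT marrow in KO host against 26.1 in WT marrow in WT host. H2-Ab1, an MHC class II chain, stood at 6578 CPM in intact KO against 1427 in intact WT, and at 2940 in WT marrow in KO host against 1199.9 in WT marrow in WT host. For host genotype, 8 of 8 MHC class II genes, 10 of 10 MHC class I genes and 18 of 18 interferon genes were higher in all 3 pairs. Over all genes 0 members of each list passed, whereas 8, 9 and 18 passed adjusted over the list alone. Camera gave adjusted p = 3.44e-11, 1.15e-09 and 1.53e-21 for the 3 lists, and with an estimated correlation adjusted p = 0.725, 0.726 and 0.725. With KO marrow the same lists were higher (camera adjusted p = 2.67e-07, 2.67e-07 and 4.02e-07, but adjusted p = 0.809 with an estimated correlation), with 5, 0 and 0 members adjusted over the list alone. With KO marrow 7 of 8, 10 of 10 and 10 of 18 members were higher in all 3 pairs.

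Single genes did not pass in either comparison by edgeR. The error of this model holds any host by marrow interaction, so this does not show that no gene changed. For host genotype 0 of 15072 genes passed, with 596 at an unadjusted p under 0.05 and 139 by DESeq2. For immune genotype 0 passed, with 572 at an unadjusted p under 0.05 and 37 by DESeq2. Lyve1, a hyaluronan receptor gene of resident macrophages, Pf4, Lyz1, Spp1 and F13a1 had lower values in all KO hosts, with fitted log2 changes of -2.29, -0.77, -1.47, -0.61 and -1.58. Chil3, a chitinase-like gene of alternative activation, stood at 284, 143 and 101 CPM with KO marrow and at 603, 636 and 690 with WT marrow (adjusted p = 0.895). Ltc4s, Rcn3 and Ankrd33b were likewise lower in every KO marrow pair, and Ly6a, Ccl5 and Dcstamp higher, without passing. The host count was 29 without WT marrow in KO host and 1 without intact WT, and the immune count 19 without KO marrow in WT host.

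The inflammatory list was higher with KO host (camera adjusted p = 0.0203) and with KO marrow (adjusted p = 0.000913), the proliferation list with KO host (adjusted p = 0.00898) and the glycolysis list with KO marrow (adjusted p = 7.57e-05). With an estimated correlation these gave adjusted p = 0.981, 0.809, 0.981 and 0.809. Lists of lipid uptake, cholesterol efflux, cholesterol synthesis, fatty acid synthesis and oxidation, suppressive macrophage genes and dissociation stress had no camera call with either factor in macrophages. In CD8 T cells the T cell receptor response, MHC class I, lipid, cholesterol, fatty acid and dissociation stress lists had none either, nor had proliferation with host genotype or the cytotoxic, exhaustion, naive and glycolysis lists with immune genotype. Median, mean and test differed in sign in CD8 T cells for fatty acid oxidation with host genotype and for the cytotoxic, exhaustion, T cell receptor response and dissociation stress lists with immune genotype, and in macrophages for dissociation stress with immune genotype. Adjusted over the list alone, the suppressive list had 1 member higher and 2 lower with KO host and 2 higher and 1 lower with KO marrow, and the inflammatory list 0 with either. For both KO the signs differed in CD8 T cells for T cell receptor response and lipid uptake.

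In macrophages, the libraries whose host and marrow were both KO stood apart from the other 4. That contrast was chosen after this was seen, so its p-values do not account for the choice. In their macrophages Cxcl9 was at 1306 and 2009 CPM against 26.1 to 178 in the other 4 libraries, a log2 fold change of 3.97 (SE 0.68, adjusted p = 0.0222). H2-K1, an MHC class I chain, rose by 1.53 (SE 0.12, adjusted p = 0.00297) and Ly6a, an interferon-inducible surface gene, by 4.34 (SE 0.65, adjusted p = 0.0161). Vsig4, a complement receptor gene, fell, with a log2 fold change of -4.16 (SE 0.21, adjusted p = 0.000839) and so did Cd163, a scavenger receptor gene, with -3.65 (SE 0.45, adjusted p = 0.00977).

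With that contrast 1978 of 15072 macrophage genes changed, 1066 higher and 912 lower. The 8 MHC class II genes, the 10 MHC class I genes and 16 of 18 interferon genes rose over all genes tested, and 8, 10 and 18 adjusted over the list alone (camera adjusted p = 5.87e-06, 4.89e-10 and 2.45e-10, and adjusted p = 0.522 with an estimated correlation). Of 15 inflammatory genes 4 rose, Nos2, the inducible nitric oxide synthase, among them at 81.4 and 125 CPM against 8.00 to 33.5 (6 adjusted over the list alone, camera adjusted p = 0.000755, and adjusted p = 0.522 with an estimated correlation). Of 14 suppressive genes 2 rose and 2 fell, with Cd274, which encodes PD-L1, at 1.63 (SE 0.14, adjusted p = 0.00402) and Mrc1, the mannose receptor, at -0.95 (SE 0.11, adjusted p = 0.00784). The glycolysis, proliferation and cholesterol synthesis lists had 3, 2 and 1 members higher over all genes and 3, 2 and 0 adjusted over the list alone (camera adjusted p = 0.000311, 0.00395 and 0.0443, and adjusted p = 0.725, 0.766 and 0.766 with an estimated correlation). In the transplanted libraries alone the glycolysis call ended (camera adjusted p = 0.0685). Cholesterol synthesis turned to lower there, without a call (0.987). Lipid uptake, cholesterol efflux, fatty acid synthesis and oxidation and dissociation stress had no camera call. Over all genes 3 of 20 lipid uptake genes rose and 1 fell, 1 of 8 cholesterol efflux genes rose and 1 fell, 2 of 16 fatty acid oxidation genes fell, and 3 of 13 dissociation stress genes fell. Adjusted over the list alone these were 4 and 1, 1 and 1, 1 higher and 2 lower, and 3 lower. Clusters 3, 6 and 12 held 32.4%, 34.7% and 8.22% of macrophages in intact KO and 49.7%, 22.7% and 8.48% in KO marrow in KO host. Clusters 1 and 2 held 40.3% and 11.5% in intact WT, 18.6% and 33.3% in KO marrow in WT host, 24.8% and 26.4% in WT marrow in KO host and 15.9% and 29.995% in WT marrow in WT host. The count was 742 without KO marrow in WT host, 832 without WT marrow in KO host, 1013 without intact WT and 1032 without intact KO, and 3358 by DESeq2.

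In CD8 T cells of those 2 libraries, the median of the interferon genes went the other way. Ifit3, an interferon-induced antiviral gene, stood at 19.0 and 10.6 CPM against 50.1 to 67.2 in the other 4 libraries, a log2 fold change of -2.12 (SE 0.25, adjusted p = 0.000747). Usp18, a negative regulator of interferon signalling, fell by 1.80 on the log2 scale (SE 0.25, adjusted p = 0.00185) and Rtp4 by 1.46 (SE 0.27, adjusted p = 0.0106). Of 18 interferon genes 3 fell and 1 rose over all genes, 4 and 2 adjusted over the list alone, and the median log2 fold change was -0.40 (camera adjusted p = 0.000206, and adjusted p = 0.416 with an estimated correlation). The gene that rose over all genes was Cxcl9. Without TMM scaling it stood at 42.0 CPM in intact KO and 42.4 in KO marrow in KO host, where free macrophage RNA alone, at the 3.03% and 2.97% that C1qa, C1qb and C1qc gave, would bring 40.9 and 54.9, so its rise was not told apart from background.

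A total of 330 genes changed in CD8 T cells with that contrast, 152 higher and 178 lower. The CD8 T cells of the 2 libraries differed in make-up. Clusters 29 and 30 held 26.2% and 24.4% of the class in KO marrow in KO host, but 3.84% each in intact KO. In WT marrow in KO host they held 3.85% each. Cluster 38 held 0.99% in KO marrow in KO host and 21.6% in intact KO. Cluster 31 was smaller in both, at 3.12% and 12.3%, than in the other 4 libraries, at 27.9% to 53.2%. Bcl2, a survival gene, fell by 1.04 on the log2 scale (SE 0.15, adjusted p = 0.00242) and Cd69, an early activation marker, by 1.30 (SE 0.17, adjusted p = 0.00118). Myo10, an unconventional myosin gene, rose by 3.30 (SE 0.41, adjusted p = 0.0105) and Dusp14, a phosphatase gene, by 2.32 (SE 0.29, adjusted p = 0.00118). The naive and memory list was lower, with 3 of 14 falling over all genes and 4 adjusted over the list alone (camera adjusted p = 2.64e-06, and adjusted p = 0.416 with an estimated correlation). The exhaustion list was higher (camera adjusted p = 0.000256), with 0 of 16 members past the threshold over all genes and 4 higher adjusted over the list alone, and so was the cytotoxic list (camera adjusted p = 0.0367), with 3 higher and 1 lower, and 3 and 2 adjusted over the list alone. Both had an adjusted p = 0.416 with an estimated correlation. Among cells without UMIs of naive genes both calls ended, with medians of 0.04 for exhaustion (camera adjusted p = 0.403) and -0.19 for the cytotoxic list (camera adjusted p = 0.91), and among cells with them the medians were 0.92 and 0.96. Cd69 belongs to the T cell receptor response list, of which 1 gene rose and 1 fell over all genes and 4 rose and 3 fell adjusted over the list alone. Proliferation, T cell receptor response, fatty acid oxidation and synthesis, lipid uptake, MHC class I and dissociation stress had no camera call, with 1 of 13 dissociation stress genes lower over all genes and 3 adjusted over the list alone. Idi1 and Slc16a3, of the cholesterol synthesis and glycolysis lists, rose by 1.30 and 1.05, and both lists were higher (camera adjusted p = 0.00793 and 0.000256, each with an adjusted p = 0.416 with an estimated correlation). Fcrls, Cbr2 and Folr2, which are abundant in macrophages, fell in CD8 T cells too, with Fcrls at 3.92 and 3.73 CPM against 34.7 to 45.8. Trdc, a gamma-delta T cell receptor gene, also fell, from 28.8 to 167 CPM in the other 4 libraries to 14.5 and 6.95. Whether Trdc followed other T cells counted in the class was not tested. The count was 132 with 100 cells per library, 70 among cells without UMIs of naive genes, 105 without KO marrow in KO host and 88 without KO marrow in WT host.

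Within the intact pair alone, which has no replicate, macrophages of intact KO held more Ly6a, Cxcl9, Nrg1, Acod1 and H2-Q7 and less F13a1, Cbr2, Fcrls, Folr2 and Mtdh. F13a1, a coagulation factor gene, stood at 90.8 CPM in intact KO and 949 in intact WT. CD8 T cells of intact KO held more Gzmd, Gzme, Myo10, Mt1 and Mt2 and less Trdc, Igfbp4, Maf, Tmem176b and Clnk. Trdc marks gamma-delta T cells, so other cells counted in the class were not told apart from a change within CD8 T cells. Mt1, a metallothionein gene, stood at 940.5 CPM against 98.5.

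**Figure D3:**
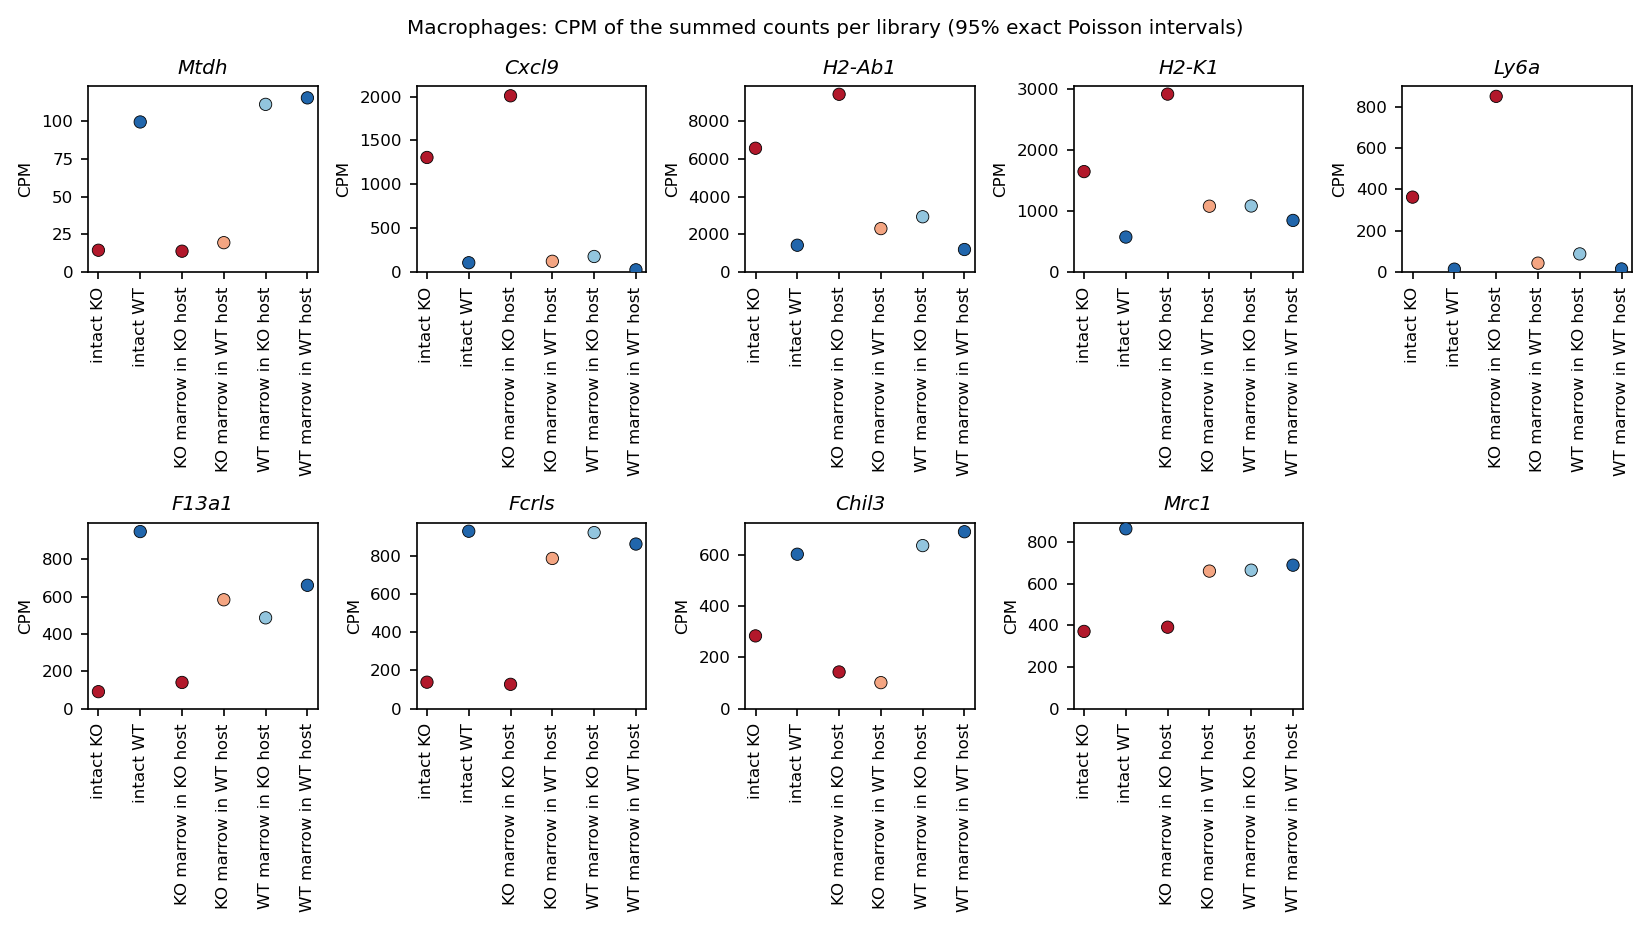
CPM of 9 genes in the summed counts of macrophages, 1 point per library with exact 95% Poisson intervals, in red for host and marrow both KO, dark blue for both WT, orange for KO marrow in WT host and light blue for WT marrow in KO host. Cxcl9 lies at 1306 and 2009 CPM in intact KO and KO marrow in KO host and at 26.1 to 178 in the other 4 libraries.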

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

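The contrast of the 2 libraries with host and marrow both KO, the interaction model, all counts of splits and the tests of the marrow label, software version, cell numbers and CD8 T cell interferon genes against naive cells were chosen after the results were seen, as were the second of 2 tests of free RNA in macrophages and the test of the direction that free macrophage RNA would give in CD8 T cells.

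In 73 of 9793 CD8 T cell genes the host effect differed between KO and WT marrow, by an interaction term with 1 residual degree of freedom. The CD8 T cell share had a host log2 ratio of 1.76 (1.7611) with KO marrow and -0.54 (-0.541) with WT marrow, a difference that was not tested. Mesenchymal cells, which a CD45-positive sort would remove, made up at most 8.89% (8.8885) of a library, in KO marrow in WT host. Cells with both T and myeloid markers made up at most 1.91% (1.908), in intact KO, and were not used in the comparisons.

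Macrophages of intact KO and of KO marrow in KO host differed alike from the other 4 libraries. A wrong marrow label is argued against by Mtdh, whose lowest macrophage level with WT marrow was, without TMM scaling, 5.82 times the highest with KO marrow. Free RNA of other cells was left open by the first test, in which 15.3% of the 1066 higher genes were more abundant in macrophages than in every other class tested. For T, B, neutrophil and mesenchymal cells it is argued against by the second test. There 96.7% of the higher genes rose by more than the free RNA measured from markers of these cells. Monocytes and dendritic cells were not sources in either test, so free RNA from them stays open. Monocytes made up 3.41% of intact KO and 9.77% of KO marrow in KO host. Software version or transplantation is argued against by the 18 of 18 interferon genes that were higher within both the intact pair and the transplanted libraries. A wrong host label stays open and untested, and a biological effect that needs KO in host and marrow together stays open, with 0 of 16076 macrophage genes past the threshold for a host by marrow interaction by edgeR (787 at an unadjusted p under 0.05, 1 residual degree of freedom).

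With host genotype, 90 genes changed in CD8 T cells, exhaustion genes among them. Free RNA of macrophages as the whole cause is argued against by the 65.6% of these genes that were more abundant in CD8 T cells than in macrophages, and unequal cell numbers by the 83 genes that passed at 100 cells per library. A smaller number of naive cells remains a candidate explanation, since the exhaustion median was 0.36 (0.362) among cells without UMIs of naive genes and 0.66 in all cells. The exhaustion list was higher in both subsets of cells (camera adjusted p = 0.0276 without such UMIs, and 0.000665 with them, where the median was 0.72). In all cells its call was lost with an estimated correlation (camera adjusted p = 0.859). Cluster 38, with Lef1 of the naive and memory list among its leading genes, was not smaller in every KO host. It held 21.6% of CD8 T cells in intact KO against 28.7% in intact WT. With KO marrow it held 0.99% in the KO host against 26.4% in the WT host. With WT marrow the direction was opposite, at 17.3% in the KO host against 2.92% in the WT host. The biological effect of host genotype is open as well.

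Where host and marrow were both KO, interferon genes had a lower median in CD8 T cells and a higher one in macrophages, though in CD8 T cells 3 of 18 fell and 1 rose over all genes and the list call was lost with an estimated correlation (adjusted p = 0.416). Fewer naive cells as the whole cause are argued against, since the median in CD8 T cells was -0.63 (-0.627, camera adjusted p = 6.03e-05) without cells that held naive-gene UMIs and -0.40 in all cells, while in cells with such UMIs it was -0.30 and the call ended (adjusted p = 0.333). Free macrophage RNA, measured with C1qa, C1qb and C1qc, is argued against by its direction, since it would be higher in both pairs for 18 of 18 of these genes. Its subtraction gave a median log2 ratio of -0.40 (-0.3951) against -0.31 without it, which decides nothing because that direction fixed the outcome. A biological difference between the classes is a hypothesis that was found and tested on the same libraries, and a wrong host label stays open.

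The 6 libraries allow too few splits for a share under 0.05. For host genotype in CD8 T cells 1 of 9 splits gave as many genes as the real 90, with 74 the highest of the others. For immune genotype 3 of 9 did, with 7 real and 41 the highest other, in the split of the intact pair with KO marrow in KO host against the rest. In macrophages 9 of 9 gave at least the real 0 for both factors, with 38 the highest other for host and 36 for immune genotype. For both KO 1 of 14 splits did in each class, with 330 real in CD8 T cells and 1978 in macrophages, and 0 the highest other. That pair was chosen because it stood apart, and its difference enters the error of the other splits. Its rank was therefore largely set in advance and decides nothing.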

How the results depend on the processing

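The alternatives with equal cell numbers, without naive-gene UMIs, without macrophage-high genes and with joined monocytes, and all those for both KO, were chosen after the data were seen. Gene counts with host and immune genotype stayed within 1.5 times under 11 and 8 alternatives other than leaving out a library in CD8 T cells, and under 11 and 9 in macrophages, and for both KO under 2 and 1. For the others, given here, the cause was not tested. CD8 T cell genes changed with host genotype (90) numbered 291 with no count filter, 34 with the marker gate and 26 without naive-gene UMIs, and 54 to 325 with a library left out. With immune genotype (7) they numbered 30 with no count filter, 1 without the other factor, 3 with doublets kept, 1 at 100 cells per library, 2 without naive-gene UMIs and 4 without macrophage-high genes, and 3 to 86 with a library left out. Macrophage genes with host genotype (0) numbered 139 by DESeq2 and 0 to 29 with a library left out. With immune genotype (0) they numbered 37 by DESeq2, 1 with no count filter, 1 without the other factor and 0 to 19 with a library left out. For both KO, CD8 T cell genes (330) numbered 132 at 100 cells, 70 without naive-gene UMIs and 88 to 488 with a library left out, and macrophage genes (1978) 3358 by DESeq2 and 742 to 1972. Of the list calls, 16 became 0 with an estimated correlation and 0 by fry, and the 13 for both KO became 0 and 1. In the transplanted libraries alone 15 and 11 lists were called. There the calls ended for macrophage inflammatory genes (adjusted p = 0.708) and CD8 T cell glycolysis (0.115) with host genotype, CD8 T cell proliferation with immune genotype (0.296), and CD8 T cell cytotoxic genes (0.0504) and macrophage glycolysis (0.0685) for both KO, and macrophage cholesterol synthesis for both KO reversed to lower (0.987). Called there only were CD8 T cell proliferation (0.00649) and macrophage dissociation stress (0.0214) with host genotype and CD8 T cell dissociation stress for both KO (0.00565). The mean log2 ratio of the CD8 T cell share kept its sign under 9 alternatives for each factor, and fell from 0.89 to 0.23 for host and from 1.82 to 0.41 for immune genotype as a share of T and NK cells alone. It was 0.45 to 1.60 and 1.15 to 2.30 with a library left out. The share test cannot reach 0.05 in this design, so its side of the threshold was fixed.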

Other observations

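The tests for both KO in this part were chosen after the data were seen. In mesenchymal cells, of 12458 genes tested by edgeR, 12 were higher with host genotype, 6 differed with immune genotype and 266 differed for both KO. Their Mtdh levels, given above, argue against a host origin of most of these cells, if the KO reaches such host cells. Krt8, an epithelial or tumour marker, was among the leading genes of clusters 11 and 24 of this class. Whether these cells are the injected Py8119 tumour cells was not tested. In neutrophils, of 6302 genes, 1 was lower with host genotype, 0 passed with immune genotype (280 at an unadjusted p under 0.05) and 160 differed for both KO. Macrophages had 0 genes of 16076 with a host by marrow interaction by edgeR, with 787 at an unadjusted p under 0.05. Monocytes made up 3.41% of intact KO, 9.77% of KO marrow in KO host and 0.63% to 1.03% of the other 4 libraries. Among clusters without a name, cluster 13 held 5.72% of KO marrow in KO host and cluster 34 held 2.83% of intact KO.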
